A study of Mus musculus with 4 samples.

How the data were processed

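Gene expression was measured by RNA-seq in 4 libraries of mouse Th17 primary cells, made by differentiation of CD4 T cells per the labels. The labels call the assay total RNA-seq and link a library protocol whose name refers to poly(A)-selected RNA. The header of each deposited table names an alignment of a 24 hour sample, a time that the labels do not give, and its replicate number matches that of the labels.

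The deposited tables hold whole-number counts of read pairs per gene, made per the file headers with featureCounts 1.4.6-p4 on GENCODE M13 exons (mm10), for reverse-stranded pairs with both ends mapped. The aligner's version is not given in the sources used here. Multi-mapping reads were not counted, per the options in the file headers, so a gene with a near-identical copy loses the reads it shares. The deposited tables also give the merged exon length of each gene. The text notes that accompany the tables hold no measurements and were not used.

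Each table holds 50600 genes. Symbols and gene types were taken from GENCODE M21 (the same assembly) by Ensembl identifier, which matched 50376 (99.6%) of them, and coordinates are those of the deposited tables. TPM was computed here from the deposited counts and exon lengths over all genes. The tests had been written for expected counts with effective lengths, and were run on the counts and exon lengths in their place. Alternatives that needed posterior mean estimates were not run.

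The level of each of 21764 protein-coding genes was tested against 1 TPM with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test of the intercept with an offset equal to the log count that 1 TPM gives, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test's steps were carried out singly because its function takes no design of 1 column. Variation between libraries was tested for genes with a mean of at least 10 counts, by the negative binomial deviance at edgeR's trended dispersion against chi-square, one-sided, with TMM normalization. Differences between lists and between genes were taken within each library as log2(TPM + 1) and tested with an exact sign-flip permutation test over libraries. Variation of a list was the SD over libraries of its mean log2(CPM + 1), compared with 10000 random lists matched in 20 bins of expression. Since no groups were compared, no splits of the libraries were drawn.

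On simulated counts with the real means and library sizes, with 100 genes changed in 1 library at each fold among 12849, the variation test recovered 72% of 2-fold and 94% of 4-fold changes with 4 false calls. Each gene was drawn at the trended dispersion, which this test assumes, so few false calls were built in. The 4 do not give the rate for real genes that stray from the trend. On 5000 genes simulated at 1 TPM, the level test recovered 99% of 100 genes at 2 TPM and 100% of 100 at 4 TPM, with 16 false calls. These genes too were drawn at the trended dispersion, and short genes were left out. No gene was simulated below 1 TPM, so the recovery of calls below it is unknown.

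Before the data were examined, 34 gene lists, the tests, their alternatives and the rule for naming genes were fixed. The rule names all members of the Th17 signature and of the Th17 transcription factor, cytokine and receptor lists, the genes of the pairs compared, the 3 highest and the lowest member of every other list by mean TPM, the 15 highest protein-coding genes outside Rpl, Rps and mt- symbols, and the 15 genes with the smallest p in the variation test. Where several members tied at 0 for the lowest, 1 is named. Values of 3 genes that the rule names, and 4 differences between pairs that need 1 of them, are not given; the lists that hold these genes keep them in their counts. Other genes were named after their values were seen: Cd8a, mt-Nd4 and the mitochondrial genes with few counts, and the genes given under other observations. A last-digit rounding of results to 9 significant digits was applied.

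Total counts ran from 19332509 to 48558772, of which 98.7% to 98.9% fell in protein-coding genes. A level of 0 is given with the TPM that 3 counts over the 4 libraries would equal, a limit that covers counting error only. Reads without molecular identifiers are not independent molecules. For each list gene, the share of 50-base words in its M21 transcripts that another gene's transcripts hold on either strand was computed as a guide to shared reads, and a level is called uncertain where the share is at least 25%, a line set after the values were seen; ribosomal protein genes and genes outside the lists were not searched, so shared reads of these are unknown. The share also counts words of a gene that overlaps on the opposite strand. Counting by strand keeps such reads apart, so the share can overstate shared reads. The alternatives were DESeq2 1.42.0, limma 3.58.1, other size factors, count filters, pseudocounts, TPM denominators, levels of 0.5 and 2 TPM, medians of lists and leaving out each replicate. A run of both variation tests with genes on X and Y left out was added after the data were seen. Python 3.11.15 with pandas 2.3.3 was used for tables.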

Results

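RNA-seq counts were available for 4 libraries of T helper 17 (Th17) cells from C57BL/6NJ mice. Th17 cells are CD4 T cells that make the cytokines IL-17A and IL-17F. The labels number the libraries as biological replicates 1 to 4 and give 1 donor entry for all of them, with sex not collected. No other cell type or condition was included, so the levels below describe 1 group. The p-values of differences within libraries measure only the spread between these 4 libraries. Those of levels rest on a dispersion shared in part with other genes, so they do not measure a gene's own spread. Ddx3y, at 77.8, 58.9, 0.240 and 0.0925 TPM in replicates 1 to 4, still had an edgeR adjusted p of 4.32e-57. The p-values for variation set a gene against the dispersion trend, or a list against random lists of genes, which are not independent. Total counts were 41360302, 19332509, 34979616 and 48558772 in replicates 1 to 4, over 16486 to 18085 genes with a count. At these depths 3 counts in a gene of 1 kb of exon equal 0.206 TPM in the deepest library and 0.518 TPM in the shallowest. Replicates correlated across genes at a Pearson r of log2(TPM + 1) from 0.994 to 0.996 and a Spearman rho from 0.919 to 0.927, where genes are not independent observations. As a check for duplicate deposits of 1 library, the counts of the 6 pairs of libraries were compared, and the chi-square per degree of freedom was 4.36 to 11.4, where duplicates would give about 1 or less.

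Il2, the gene of the T cell growth factor interleukin 2, was among the 15 most abundant protein-coding transcripts outside the ribosomal protein genes and the mitochondrial genome. Eef1a1, a translation elongation factor, stood highest at 9129 ± 283 TPM (SD, n = 4), followed by the chaperone Hsp90ab1 at 8812 ± 191 TPM, Eef2 at 6097 ± 83.1 TPM and Actb at 5752 ± 146 TPM. Il2 came next of these at 5738 ± 341 TPM, 9th among all protein-coding genes. The other genes of the highest 15 were Npm1, Eif5a, Ldha, Hnrnpa1, Pkm, Hspd1, Tubb5, Ptma, Hspa8 and Mif, between 2069 TPM for Mif and 5365 TPM for Npm1. Pkm and Hspa8 share 25.8% and 39.4% of their 50-base words with other genes, so their levels are uncertain. Of 21764 protein-coding genes, 9989 lay above 1 TPM, 11213 below and 562 on neither side, by edgeR's quasi-likelihood test of the level with Benjamini-Hochberg adjustment at 0.05. The count below 1 TPM was 1165 with DESeq2's Wald test and 761 among genes with a mean of at least 10 counts.

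The question the cell label raises is whether these libraries carried the Th17 programme, and Il17a and Il17f were expressed in all 4. Il17f (mm10 chromosome 1, 20777146 to 20790617, ENSMUSG00000041872) reached 492 ± 71.4 TPM (SD, n = 4), while its neighbour Il17a (mm10 chromosome 1, 20730905 to 20734496, ENSMUSG00000025929) stood at 46.0 ± 6.13 TPM. Il22, a cytokine that acts on epithelia, was at 118 ± 22.1 TPM, with 41.0% of its 50-base words shared with the annotated copy Iltifb, so its level is uncertain. Of the 12 genes of the Th17 signature, 10 lay above 1 TPM, 1 below and 1 on neither side, and the counts were identical adjusted over the list alone. Other members above 1 TPM were the nuclear receptor gene Rora at 16.4 ± 1.42 TPM, the cytokine and chemokine receptor genes Il23r at 14.4 ± 2.70 TPM, Il1r1 at 27.5 ± 1.46 TPM, Ccr6 at 21.01 ± 4.39 TPM and Cxcr6 at 6.36 ± 1.34 TPM, and the ligand-activated factor Ahr at 29.8 ± 6.25 TPM. Ccl20, the chemokine ligand of Ccr6, gave 0.520, 2.68, 1.15 and 1.01 TPM in replicates 1 to 4 and was on neither side of 1 TPM (edgeR adjusted p = 0.344). Il17re, a receptor subunit for IL-17C, was below 1 TPM at 0.0870 ± 0.0318 TPM, a call that DESeq2's Wald test did not make.

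All 12 Th17 transcription factors lay above 1 TPM, over all genes tested and adjusted over the list alone. Batf, Junb and Irf4, which bind DNA together at T cell enhancers, were the highest at 787 ± 33.4 TPM, 738 ± 33.2 TPM and 639 ± 34.2 TPM (SD, n = 4). Hif1a stood at 295 ± 12.4 TPM, Stat3, which transmits IL-6 and IL-23 signals, at 140.0 ± 5.03 TPM, and Nfkbiz at 97.4 ± 5.18 TPM. Runx1, Fosl2 and Maf were lower, at 34.1 ± 1.76 TPM, 30.6 ± 1.55 TPM and 8.86 ± 1.60 TPM. All 10 Th17 cytokine receptor genes were above 1 TPM by both adjustments. Il2rb, Il2rg and Il12rb1 led them at 372 ± 17.3 TPM, 351 ± 9.26 TPM and 293 ± 6.73 TPM, followed by Il21r at 245 ± 10.7 TPM, and the level of Il2rg is uncertain because it shares 27.5% of its words with other genes. The IL-6 receptor genes Il6st and Il6ra were at 42.2 ± 4.80 TPM and 16.2 ± 1.21 TPM, and the TGF-beta receptor genes Tgfbr2 and Tgfbr1 at 35.9 ± 2.01 TPM and 17.7 ± 0.788 TPM.

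Of the 12 Th17 cytokines and chemokines, 10 lay above 1 TPM, 1 below and 1 on neither side, with the same counts adjusted over the list alone. Tnf was at 512 ± 12.97 TPM, Lif at 396 ± 8.69 TPM, Il21 at 209 ± 12.7 TPM and Tgfb1 at 87.2 ± 2.80 TPM (SD, n = 4). Tnfsf11, the gene of RANK ligand, stood at 33.1 ± 2.68 TPM, Csf2, the gene of GM-CSF, at 15.9 ± 3.85 TPM, and Il9 at 6.42 ± 1.45 TPM. Il10, which codes for an anti-inflammatory cytokine, was below 1 TPM at 0.438 ± 0.203 TPM (edgeR adjusted p = 0.0163). That call was lost without replicate 1 (edgeR adjusted p = 0.0693), without replicate 3 (edgeR adjusted p = 0.0781) and with DESeq2's Wald test (adjusted p = 0.654).

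Each of the 16 genes of the pathogenic Th17 list, drawn from Th17 cells that cause autoimmune disease, was also placed against 1 TPM. Of these, 13 were above, 1 below and 2 on neither side, and adjusted over the list alone the counts were the same. The chemokine gene Ccl4 was at 148 ± 13.3 TPM and the costimulatory receptor gene Icos at 127 ± 2.53 TPM (SD, n = 4), and Ifng was the lowest member at 0.230 ± 0.222 TPM. With DESeq2's Wald test 12 were above and 0 below. In the non-pathogenic Th17 list 6 of 7 genes were above 1 TPM and Il10 below, again by both adjustments, and DESeq2's Wald test placed 0 below. Cd5l, a regulator of lipid metabolism in Th17 cells, was its highest member at 65.9 ± 7.41 TPM.

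Regulators and cytokines of other T helper subsets were measured beside these. The levels were 26.6 ± 0.642 TPM (SD, n = 4) for Tbx21, the Th1 regulator, 14.0 ± 1.18 TPM for Bcl6, the follicular helper regulator, 3.78 ± 0.790 TPM for Gata3, the Th2 regulator, and 0.0877 ± 0.0730 TPM for Foxp3, the regulatory T cell regulator. Among cytokines, Il17a exceeded Ifng by 5.27 ± 0.40 on the log2(TPM + 1) scale, Il4 by 5.38 ± 0.28 and Il10 by 5.03 ± 0.29, while it was lower than Il17f, with a difference of -3.39 ± 0.14. With a pseudocount of 0.1 the differences from Ifng, Il4 and Il10 were 7.41, 7.92 and 6.49, so their size depends on the pseudocount. Ifng gave 0, 0.133, 0.519 and 0.265 TPM and Il4 0, 0, 0.235 and 0.280 TPM in replicates 1 to 4. All 4 differences had the same sign in 4 of 4 libraries. The exact sign-flip permutation test over 4 libraries, two-sided, gave each its smallest possible p of 0.13, so none can pass 0.05. DESeq2's Wald test placed none of Foxp3, Ifng and Il4 below 1 TPM, where edgeR placed all 3.

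**Figure D1:**
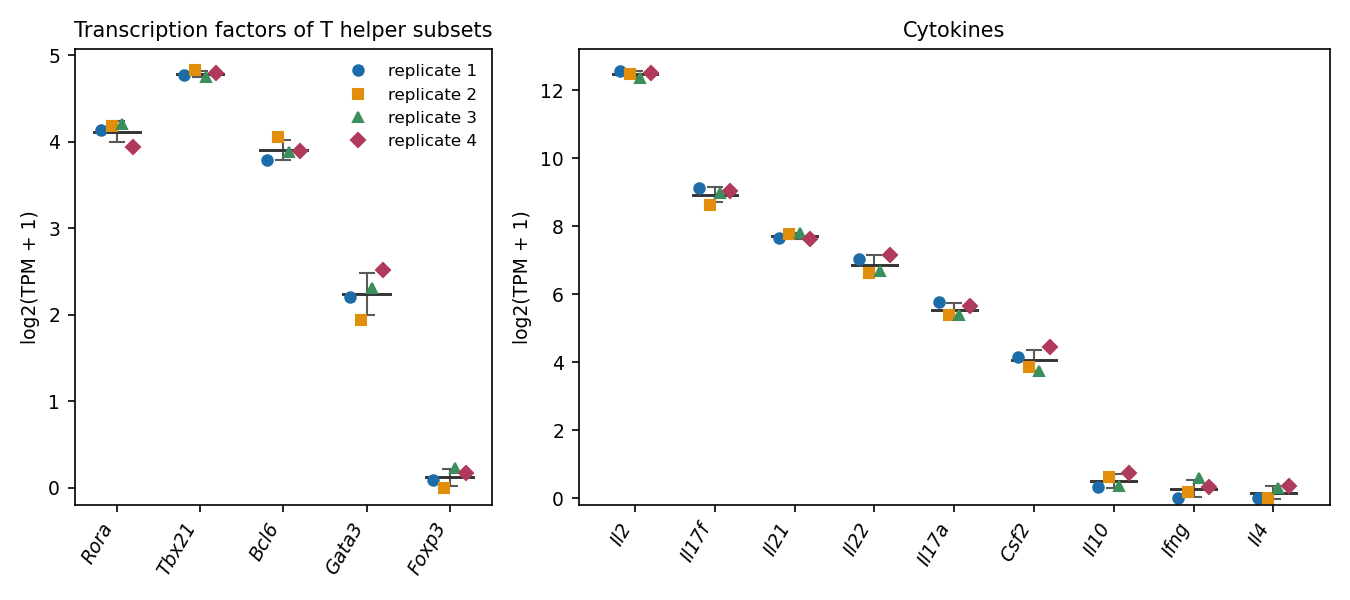
Levels of transcription factor genes of T helper subsets (left) and of cytokine genes (right), as log2(TPM + 1), in the 4 Th17 libraries. Points are libraries, horizontal lines the mean and bars the SD; Tbx21 stands at 26.6 TPM on average, and Il10, Ifng and Il4 lie under 1 TPM in each library.

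Across whole signatures, the mean log2(TPM + 1) of the Th17 list was above those of the Th1, Th2 and regulatory T cell lists in all 4 libraries, and below that of the follicular helper list. The difference was 1.79 ± 0.06 (SD, n = 4) from the Th1 signature, 1.83 ± 0.08 from the Th2 signature and 1.09 ± 0.08 from the regulatory T cell signature. The last 2 were 2.80 and 1.86 with a pseudocount of 0.1, and 3.22 and 3.79 with medians of the lists. From the follicular helper signature it was -0.43 ± 0.07, and the sign turned when medians of the lists were compared, to 0.70 ± 0.22. Each of these differences had an exact two-sided sign-flip permutation p of 0.13, the smallest that 4 libraries allow.

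Members of every other subset's list were expressed. In the Th1 signature 9 of 12 genes lay above 1 TPM and 3 below, with Runx3 at 58.1 ± 2.06 TPM, Stat4 at 38.6 ± 4.89 TPM and Eomes the lowest at 0.184 ± 0.152 TPM (SD, n = 4). In the Th2 signature 5 of 10 were above and 5 below: Stat6, which transmits the IL-4 signal, was at 220.0 ± 3.51 TPM, the chemokine receptor genes Ccr8 and Ccr4 at 78.6 ± 1.47 TPM and 52.7 ± 5.28 TPM, and Ptgdr2 at 0.0130 ± 0.0260 TPM, a level that is uncertain because the gene shares 37.8% of its words with other genes. In the regulatory T cell signature 5 of 11 were above and 6 below, with the inhibitory receptor gene Ctla4 at 596 ± 31.8 TPM, the IL-2 receptor gene Il2ra at 561 ± 33.7 TPM and Tnfrsf18 at 178 ± 4.05 TPM, beside Lrrc32 at 0.0614 ± 0.0764 TPM. In the follicular helper signature 8 of 9 were above and 1 below: Cd200 and the inhibitory receptor genes Btla and Pdcd1 stood at 709.5 ± 21.1 TPM, 665 ± 8.73 TPM and 314 ± 14.7 TPM, and Ascl2 at 0.0613 ± 0.0709 TPM. The counts of these 4 lists were the same adjusted over the list alone. The calls below 1 TPM depend on the method: DESeq2's Wald test placed 0 genes below it in the Th1, regulatory and follicular helper signatures and 1 in the Th2 signature. It placed 7 above in the Th1 signature, 5 in the Th2, 5 in the regulatory and 7 in the follicular helper signature.

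The cells carried the transcripts of activated, dividing T cells. All 15 T cell activation genes were above 1 TPM, from the orphan receptor gene Nr4a3 at 36.8 ± 1.42 TPM to Myc at 753 ± 26.1 TPM, Tnfrsf4, the gene of OX40, at 1182 ± 57.3 TPM and Il2 (SD, n = 4). All 18 proliferation genes were above 1 TPM, with the replication genes Pcna, Mcm3 and Rrm2 at 743 ± 31.3 TPM, 713 ± 18.5 TPM and 629 ± 57.3 TPM and the mitotic cyclin gene Ccnb2 the lowest at 16.2 ± 2.13 TPM. All 17 glycolysis genes were above it: Ldha, lactate dehydrogenase A, at 3523 ± 116 TPM, Pkm at 2428 ± 51.6 TPM, Gapdh at 1586 ± 12.5 TPM and the glucose transporter gene Slc2a3 the lowest at 20.5 ± 1.09 TPM. All 17 cholesterol synthesis genes were above it too, with the regulator Srebf2 at 206 ± 5.74 TPM, Hmgcs1 at 138 ± 3.82 TPM, Cyp51 at 137 ± 3.19 TPM and Fdps the lowest at 10.6 ± 0.662 TPM. Pkm, Gapdh and Fdps share 25.8%, 25.1% and 26.2% of their words with other genes, so their levels are uncertain. Of the 82 ribosomal protein genes, taken as symbols of Rpl or Rps followed by a digit, 80 were above and 2 below. Within this list Rpl8 at 7058 ± 169 TPM, Rpl4 at 5822 ± 73.8 TPM and Rps2 at 5050.2 ± 246 TPM were the highest. Ribosomal protein genes with other symbols were not in the list and may stand higher. Rpl10l had no count, which allows up to 0.0683 TPM from 3 counts over the 4 libraries. Each of these counts was the same adjusted over the list alone, while DESeq2's Wald test placed 0 ribosomal protein genes below.

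Genes of naive and of all T cells were expressed beside them. All 10 naive and memory T cell genes were above 1 TPM by both adjustments, Tcf7 at 435 ± 12.5 TPM, the lymph node homing receptor gene Ccr7 at 275 ± 14.5 TPM and Satb1 at 183 ± 3.50 TPM, with Klf2 the lowest at 2.03 ± 0.788 TPM (SD, n = 4), and 8 were above with DESeq2's Wald test, which did not make the call of Klf2. Of the 17 pan T cell genes the 14 protein-coding ones were above 1 TPM, and all 17 adjusted over the list alone, including the antigen receptor constant genes Trac at 1163 ± 13.2 TPM and Trbc2 at 810.5 ± 51.5 TPM, the latter uncertain with 44.0% of its words shared with other genes. Cd5 was the highest at 1985 ± 36.1 TPM and Cd3g the lowest at 49.8 ± 4.64 TPM. In the p53 and apoptosis list 10 of 10 genes were above 1 TPM, with Ccng1 at 675 ± 31.3 TPM, the cell cycle inhibitor gene Cdkn1a at 545 ± 43.4 TPM, Bax at 463 ± 19.96 TPM and Bcl2l11 at 5.00 ± 0.629 TPM. In the TGF-beta response list 9 of 10 were above and 1 below, with Ski at 155 ± 2.55 TPM, Tgfb1 at 87.2 ± 2.80 TPM, Skil at 54.1 ± 2.99 TPM and the integrin gene Itgae the one below at 0.236 ± 0.0898 TPM. Stress and immediate early genes were above in 9 of 12, below in 2 and neither in 1, from the heat shock genes Hspa8 at 2107 ± 66.4 TPM and Hsp90aa1 at 1494 ± 49.9 TPM and Ier2 at 388 ± 15.2 TPM to Hspa1a at 0.289 ± 0.101 TPM. Hspa8, Hsp90aa1 and Hspa1a share 39.4%, 47.5% and 66.3% of their words with other genes, so their levels are uncertain. Of 14 interferon-stimulated genes 5 were above, 8 below and 1 neither: Bst2 and Ifih1 stood at 225 ± 18.2 TPM and 4.46 ± 0.456 TPM, and Rsad2 had no count, which allows up to 0.0161 TPM. The counts of these 4 lists did not change adjusted over the list alone. DESeq2's Wald test placed 0 genes of the TGF-beta response list below 1 TPM and 7 above, 0 of the stress list below and 8 above, and 2 of the interferon-stimulated list below and 4 above. It gave Rsad2 no p.

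Markers of other blood and tissue cells lay mostly below 1 TPM by edgeR's test, though few of these calls were made by DESeq2. Of 8 neutrophil genes all were below, with no count of S100a8 or S100a9, which allows up to 0.101 and 0.134 TPM, and Csf3r at 0.00569 ± 0.0114 TPM (SD, n = 4). All 7 erythroid genes were below, with Hbb-bs at 0.0562 ± 0.112 TPM and no count of Hba-a1 (up to 0.0860 TPM). Hbb-bs shares 53.2% of its words with Hbb-bt and Hba-a1 72.3% with Hba-a2, so both levels and this limit are uncertain. Of 5 platelet genes 4 were below and 1 neither, with no count of Pf4 (up to 0.0969 TPM) or Ppbp (up to 0.0645 TPM) and the integrin gene Itga2b at 0.930 ± 0.0715 TPM. Of 12 macrophage and dendritic cell genes 10 were below, with no count of the lysozyme gene Lyz2 (up to 0.0531 TPM) and Fcgr3 at 0.182 ± 0.151 TPM; Cst3 at 75.9 ± 3.51 TPM and Cd68 at 6.12 ± 0.885 TPM were above. Of 9 CD8 T and NK cell genes 6 were below, including Klrb1c with no count (up to 0.0236 TPM) and Cd8a. Prf1 was neither at 1.19 ± 0.724 TPM, and Cd8b1 at 14.4 ± 1.4 TPM and Nkg7 at 2.15 ± 0.743 TPM were above. The call of Cd8a was not made by DESeq2's Wald test (adjusted p = 0.187). Of 8 stromal and epithelial genes 6 were below, including Krt18 at 0.0995 ± 0.130 TPM and Krt8 with no count (up to 0.0387 TPM, uncertain because the gene shares 29.7% of its words with other genes), while the adhesion genes Pecam1 at 11.2 ± 0.577 TPM and Epcam at 1.54 ± 0.177 TPM were above. The counts of these 6 lists were identical adjusted over the list alone. DESeq2's Wald test gives no p where no library has a count. It placed 1 neutrophil gene and 1 macrophage and dendritic cell gene below 1 TPM and 0 genes of the other 4 lists, and did not place Nkg7 or Epcam above.

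Genes of B cells and gamma-delta T cells were mostly below 1 TPM or near it, apart from Ighm. All 7 protein-coding B cell genes were below 1 TPM, among them Cd79b at 0.337 ± 0.198 TPM and Ms4a1, the gene of CD20, at 0.00777 ± 0.0155 TPM (SD, n = 4). Adjusted over the list alone, 7 of the 9 genes were below, Igkc at 0.596 ± 0.495 TPM was neither, and Ighm, the immunoglobulin mu constant gene, was above at 74.1 ± 5.17 TPM. DESeq2's Wald test placed 5 of the 7 below 1 TPM, without Cd79b. In the gamma-delta T cell list 1 of the 2 protein-coding genes was below and Sox13 was neither at 1.08 ± 0.109 TPM. Adjusted over the list alone, 5 of 7 were below and 2 neither, with Trdc at 0.820 ± 0.244 TPM, Tcrg-C1 at 0.0260 ± 0.0520 TPM and no count of Tcrg-C2 (up to 0.0764 TPM). Tcrg-C1 and Tcrg-C2 share 34.2% and 25.4% of their words with other genes, so this level and this limit are uncertain.

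The mitochondrially encoded protein genes fell into those with 122 to 83848 counts per library and those with almost none. Of 13, 7 were above 1 TPM and 6 below, by both adjustments. With DESeq2's Wald test 7 were above and 0 below, since 5 of the 6 have no count and so no p, and mt-Atp6 was on neither side (adjusted p = 0.222). The highest were mt-Co1 at 3647 ± 64.9 TPM, mt-Nd1 at 3324 ± 347 TPM and mt-Cytb at 2074 ± 147 TPM (SD, n = 4). No count was found of mt-Nd3, mt-Nd4l, mt-Co2, mt-Co3 or mt-Atp8 in any library, and mt-Atp6 had 3 counts in replicate 3 alone. Apart from mt-Atp8, these genes share at least 98.0% of their 50-base words with another annotated gene, and the counts leave out reads that map to several places, so their levels are uncertain. Of the genes with more counts, mt-Co1 shares 51.1% and mt-Nd4 62.2%, so their levels are uncertain too.

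**Figure D2:**
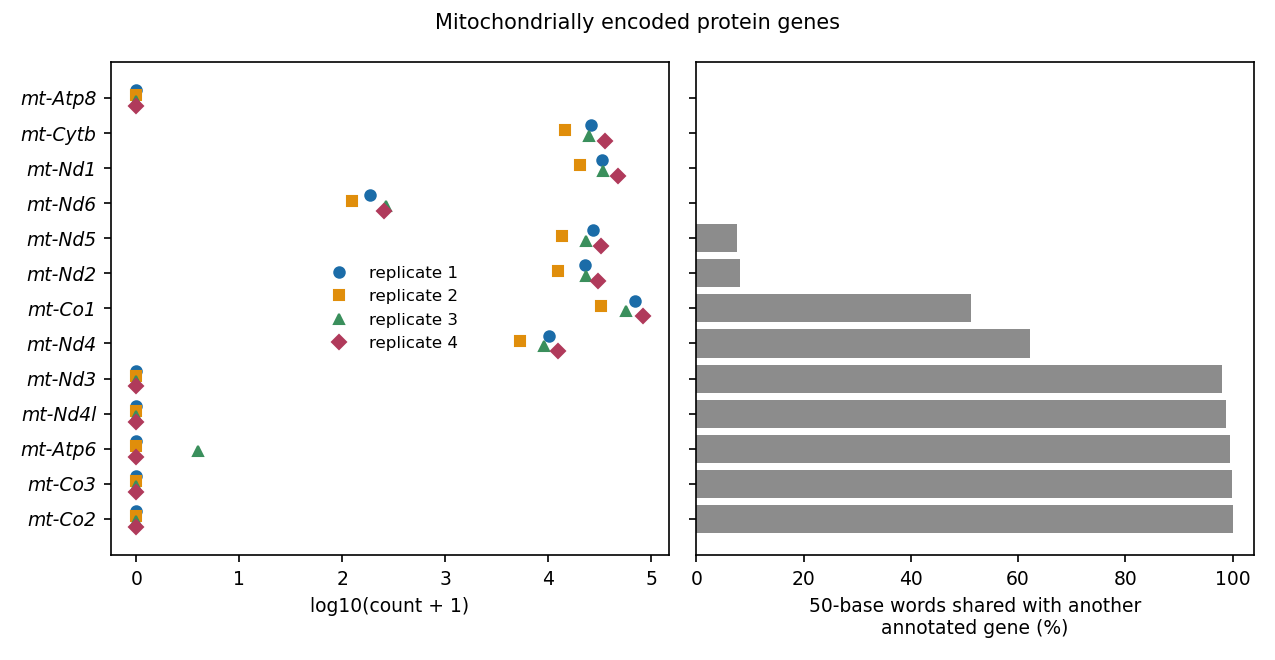
Counts of the 13 mitochondrially encoded protein genes in each of the 4 Th17 libraries, as log10(count + 1) (left), and the percent of each gene's 50-base words that another annotated gene also holds (right). Points are libraries and bars single percentages; mt-Nd3, mt-Nd4l, mt-Atp6, mt-Co2 and mt-Co3 share at least 98.0% of their words and have between 0 and 3 counts, as does mt-Atp8, which shares none.

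RNA classes that differ between library types were measured as well. Of 66 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 25 were above 1 TPM, 21 below and 20 neither, and 25, 20 and 21 adjusted over the list alone, while DESeq2's Wald test placed 13 above and 0 below. The highest were Hist1h4i at 34.3 ± 3.95 TPM, Hist1h2bj at 17.5 ± 2.72 TPM and H1f0 at 14.1 ± 1.24 TPM (SD, n = 4), the last a histone gene that is not tied to replication, and Hist2h3c2 had no count (up to 0.0685 TPM). Hist1h4i, Hist1h2bj and Hist2h3c2 share 28.9%, 59.4% and 63.5% of their words with other genes, so their levels and this limit are uncertain. Of 11 RNAs without a poly(A) tail, none of them protein-coding, 5 were above, 1 below and 5 neither adjusted over the list alone. Among these, Rpph1 was at 122 ± 17.4 TPM, Snora73b at 116 ± 20.3 TPM and Snora73a at 33.9 ± 6.03 TPM, with 68.2% of the words of Rpph1 and all of those of the other 2 shared with other genes, so these levels are uncertain, and Rny3 had no count (up to 0.685 TPM). Of 6 nuclear long non-coding RNAs 3 were above and 3 below adjusted over the list alone: Gm26917 at 262 ± 42.8 TPM, Malat1 at 81.5 ± 6.00 TPM and Neat1 at 3.49 ± 0.286 TPM were above, and Meg3 had no count (up to 0.00386 TPM).

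The libraries differed most in sex-linked genes. Xist, the RNA that coats the inactive X chromosome (mm10 chromosome X, 103460375 to 103483217, ENSMUSG00000086503), gave 0.916, 1.01, 154 and 152 TPM in replicates 1, 2, 3 and 4. The Y-linked genes were the reverse, with 77.8, 58.9, 0.240 and 0.0925 TPM for Ddx3y, 53.7, 71.1, 0.185 and 0.132 TPM for Eif2s3y, 8.77, 7.32, 0.0190 and 0.0498 TPM for Kdm5d and 6.82, 6.46, 0.00981 and 0.0210 TPM for Uty. Tsix, antisense to Xist and counted by strand, gave 1 count in replicate 3 alone. It shares 33.3% of its words with other genes, Xist above all, but counting by strand keeps reads of the opposite strand apart. The level of Tsix is uncertain because it rests on 1 count. The X-linked partners of these Y genes also differed: Eif2s3x gave 112, 108, 183 and 177 TPM, Kdm6a 21.03, 18.9, 31.8 and 33.5 TPM and Kdm5c 98.6, 93.8, 133 and 131 TPM. Over all 4 libraries, 4 of the 4 protein-coding genes of the sex-linked list were called above 1 TPM, and 5 of 6 genes above and 1 below adjusted over the list alone, but limma on log2(TPM + 1) called none of the protein-coding ones and DESeq2's Wald test 2. Means over these libraries are not meaningful for these genes.

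**Figure D3:**
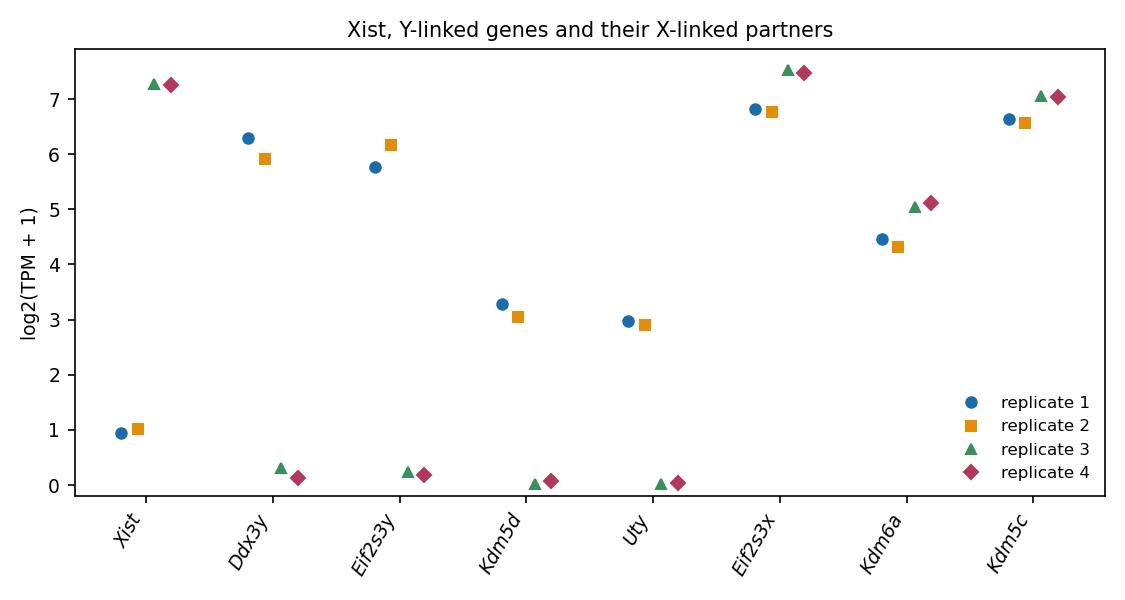
Levels of Xist, of 4 Y-linked genes and of X-linked partners of these, as log2(TPM + 1), in each of the 4 Th17 libraries. Points are libraries, with no mean or error drawn; Xist stands at 154 and 152 TPM in replicates 3 and 4 and at 0.916 and 1.01 TPM in replicates 1 and 2, and the Y-linked genes are reversed.

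Genes on the sex chromosomes and on autosomes varied more than the dispersion trend. Of 12849 genes with a mean of at least 10 counts, 48 varied more than the dispersion trend (edgeR negative binomial deviance, Benjamini-Hochberg adjusted p under 0.05), of which 8 lie on X, 5 on Y and 35 on autosomes. The number was 84 with genes on X and Y left out, an alternative added after the data were seen, and 168 with DESeq2's dispersion trend. The unadjusted p was under 0.05 for 633 genes, near the 642 that uniform p-values would give. The trend was fitted to these same genes, so this number cannot show that variation was at chance level. Against counting error alone 6199 genes were called. The common coefficient of variation between libraries was 6.64%. Gm42418, a non-coding RNA gene (mm10 chromosome 17, 39846958 to 39848788, ENSMUSG00000098178) on the strand opposite an annotated ribosomal RNA gene, gave 670.0, 660.3, 2008 and 1762 CPM (counts scaled to library size) in replicates 1 to 4, and its neighbour Gm26917 gave 211, 234, 299 and 298 CPM. The other named genes in this test were Gm42047 with 82.0, 61.7, 61.2 and 96.5 CPM, Gm23935 with 81.4, 92.6, 121 and 89.0 CPM, the Y-linked Gm29650 with 2.36, 1.91, 0 and 0 CPM, Xlr3b with 3.40, 0.361, 1.30 and 1.77 CPM, Eps8l1 with 0.820, 1.80, 1.04 and 3.97 CPM and Rbm44 with 1.18, 2.68, 1.01 and 4.10 CPM. Without replicate 4 the number of genes was 24, of which 18 were among the 48, and the calls of Gm42047 (edgeR adjusted p = 0.0696), Gm26917 (0.111), Rbm44 (0.539) and Eps8l1 (1.00) ended. The call of Gm23935 ended without replicate 3 (edgeR adjusted p = 1.00), that of Xlr3b without replicate 1 (0.209) or 2 (0.185), and that of Gm26917 also without replicate 1 (0.0735) or 3 (0.105).

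Among the Th17 genes, Ahr, Il17f and Il6st were more variable than the trend. Ahr, a receptor for dietary and environmental ligands, gave 56.0, 57.7, 66.2 and 38.9 CPM in replicates 1 to 4 (edgeR adjusted p = 8.41e-05), Il17f gave 331, 236, 304 and 316 CPM (edgeR adjusted p = 0.0376) and Il6st 149, 140.1, 151 and 118 CPM (edgeR adjusted p = 0.0169). Ahr and Il6st were no longer called without replicate 4 (edgeR adjusted p = 1.00 for both), nor was Il6st without replicate 3 (0.263) or among genes with a mean of at least 1 count (0.184). The call of Il17f was lost when any of replicates 2, 3 and 4 was left out, with edgeR adjusted p of 1.00, 0.133 and 0.233, and among genes with a mean of at least 50 counts (0.0727). Il17a (edgeR adjusted p = 1.00) and Il22 (0.0654) were not called.

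Gene lists were tested for variation as sets, against 10000 random lists of the same size and expression. Genes are not independent, so the p, a share of these random lists, only describes these libraries. The proliferation genes varied together, with a mean log2(CPM + 1) that deviated by 0.03, -0.08, -0.07 and 0.12 in replicates 1 to 4 (adjusted permutation p = 0.0125, one-sided). The pathogenic Th17 genes deviated by 0.02, -0.08, -0.07 and 0.13 (adjusted permutation p = 0.0242), the non-pathogenic Th17 genes by -0.04, 0.02, 0.15 and -0.14 (0.0125), the Th17 transcription factors by -0.02, 0.03, 0.08 and -0.09 (0.0242) and the Th17 signature by 0.06, -0.12, 0.03 and 0.03 (0.0242). Ahr is in the non-pathogenic, transcription factor and signature lists, so these results are not separate. With medians of the lists, the pathogenic (adjusted permutation p = 0.873), non-pathogenic (0.512), transcription factor (0.859) and signature lists (0.0641) were not called. In all, 13 of 25 lists with at least 5 measured members passed an adjusted p of 0.05. The other 8 were the pan T cell, T cell activation, mitochondrially encoded, p53 and apoptosis, ribosomal protein, histone and sex-linked genes and the RNAs without a poly(A) tail. The 12 lists not called included the signatures of Th1 (adjusted permutation p = 0.713), Th2 (0.0511), regulatory (0.110) and follicular helper T cells (0.765). The Th2 signature was called without replicate 1 (adjusted permutation p = 0.0447) and against random lists without genes on X and Y (0.0386). Without replicate 4 only 7 lists were called, and the calls of the pathogenic Th17 (adjusted permutation p = 0.209), non-pathogenic Th17 (0.0509), activation (0.0867), p53 and apoptosis (0.0665) and histone genes (0.311) and of the RNAs without a poly(A) tail (0.0665) ended. Without replicate 1 those of the pan T cell (adjusted permutation p = 0.789), activation (0.208), mitochondrial (0.204) and ribosomal protein genes (0.659) and of the RNAs without a poly(A) tail (0.447) ended. The Th17 signature was not called without replicate 2 (adjusted permutation p = 0.677), nor the non-pathogenic Th17 (0.107) and histone genes (0.197) without replicate 3. The histone genes were also not called with a mean of at least 50 counts (adjusted permutation p = 0.326), where the Th17 cytokines and chemokines were (0.0194). With medians of the lists 7 were called, of which 4 were among the 13, namely the activation, proliferation, p53 and apoptosis and sex-linked genes. The other 3 were the regulatory T cell signature (adjusted permutation p = 0.0482), the Th17 cytokines and chemokines (0.0117) and the Th17 cytokine receptors (0.0237). The proliferation and sex-linked genes were called under each alternative run.

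**Figure D4:**
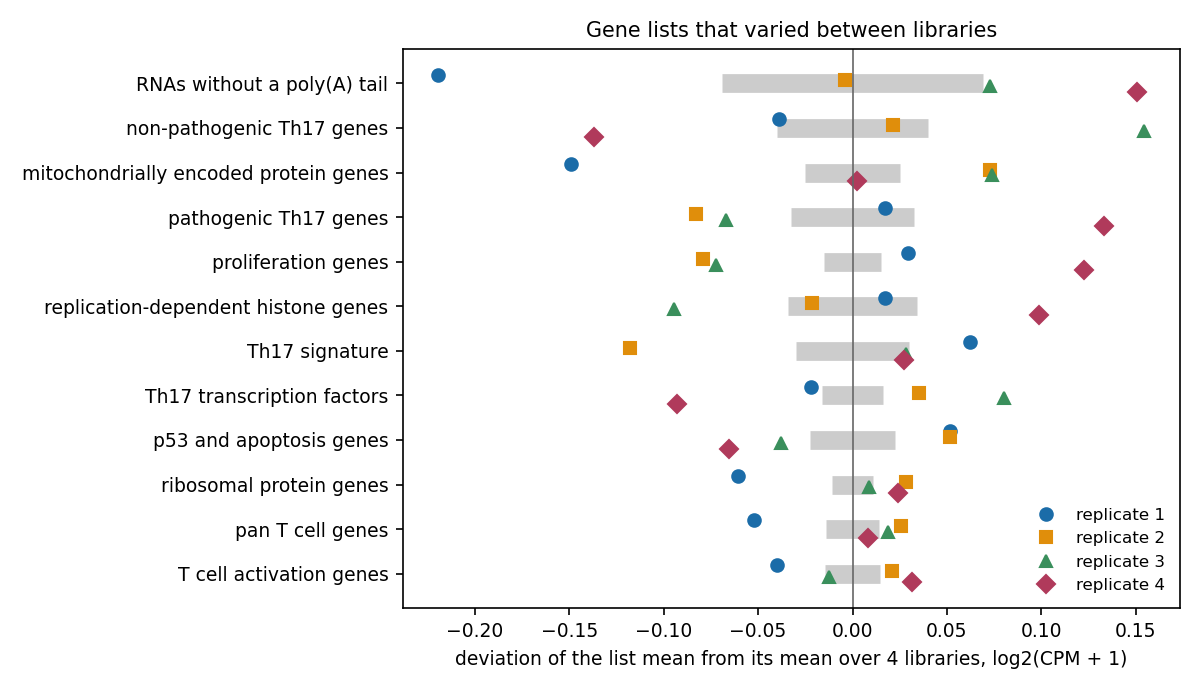
Deviation of each list's mean log2(CPM + 1) in each of the 4 Th17 libraries from its mean over them, for the 12 lists, sex-linked genes left out, that varied more than random lists. Points are libraries, and each grey band spans 1 median SD of random lists on either side of 0; the proliferation genes deviate by 0.12 in replicate 4 and by -0.08 in replicate 2.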

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

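In each set of 4 library values, the highest or lowest was marked when its gap to the nearest other value took a share of the range above Dixon's 95% critical value for 4 values. Of 205 sets 13 were marked, where chance gives about 1 in 20, or 10.2. That rate does not hold for sets with 3 libraries at 0, which are marked by construction and make up 7 of the 13, so the number of marks was not compared with chance.

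Among expressed genes, the marks fell on receptor genes, a glucose transporter gene and the perforin gene. Il2rb was 346 TPM in replicate 2 against 379 to 383 TPM in the others, Tnfrsf18 was 172 TPM in replicate 1 against 179.7 to 181 TPM, and Ccr8 was 80.8 TPM in replicate 3 against 77.8 to 78.0 TPM. The glucose transporter gene Slc2a3 was 22.1 TPM in replicate 1 against 19.8 to 20.2 TPM, and the perforin gene Prf1 was 2.27 TPM in replicate 2 against 0.794 to 0.893 TPM. The nuclear long non-coding RNAs had a mean log2(TPM + 1) of 2.81 in replicate 1 against 2.86 to 2.87 in the others.

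Further marks came from genes counted in a single library and at 0 in the other 3. Replicate 3 gave 0.0311 TPM of Ms4a1, 0.104 TPM of Tcrg-C1 and 0.0158 TPM of Tsix. Replicate 4 gave 0.0519 TPM of Ptgdr2, replicate 2 gave 0.225 TPM of Hbb-bs, and replicate 1 gave 0.0227 TPM of Csf3r, which alone set the mean log2(TPM + 1) of the neutrophil genes to 0.00406 there.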

How the results depend on the processing

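The run without genes on chromosomes X and Y was added after the data were seen. Genes above 1 TPM stayed within 1.5 times of 9989 under all 13 alternatives (9174 to 10450). Genes below 1 TPM numbered 1165 with DESeq2, which gives no p where no library has a count, and 761 with at least 10 counts, a filter that removes low genes. Missing p-values are only part of the drop with DESeq2. Of 105 list members below with edgeR, it gave 47 no p and placed 11 below. Genes more variable than the trend numbered 48, and 84 without X and Y genes (35 shared), 168 with DESeq2's dispersion trend, 6199 against counting error alone, and 24 to 40 with a replicate left out. Lists that varied together numbered 13, and 7 with medians and 7 to 12 with a replicate left out. The cause was not tested.

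A pseudocount of 0.1 widened the differences from the Th1, Th2 and regulatory T cell signatures to 2.13, 2.80 and 1.86, and moved that from the follicular helper signature to -0.35. It moved Il17a over Ifng, Il4 and Il10 to 7.41, 7.92 and 6.49, since low genes carry less weight with a larger pseudocount. With medians the 4 signature differences were 2.05, 3.22, 3.79 and, with the sign turned, 0.70; the cause was not tested. The lowest Pearson r between libraries was 0.984 with a pseudocount of 0.1 and 0.985 over genes at or above 1 TPM. Mean TPM of named genes moved by over 1 SD in 65 values, each with TPM taken over protein-coding genes, and by less in 883. Of 417 list members with a call, DESeq2 placed 73 on neither side and gave 47 with no count no p, and of 105 below 1 TPM with edgeR it placed 11 below. Leaving out a replicate ended the call of 11, and 0 turned at the 1 TPM level. In a gene of 1 kb, 3 counts equal 0.206 to 0.518 TPM, so levels under these rest on fewer counts. Alternatives with posterior mean estimates were not run. No paired analysis was possible because the study has 1 group.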

Other observations

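The cytokine scan, the antigen receptor shares, the test on sex-linked genes and the test on the neighbours of mt-Atp8 were chosen after the data or an earlier test's result were seen. Of 107 protein-coding cytokine and chemokine genes picked by symbol, 26 lay above 1 TPM, 75 below and 6 on neither side (edgeR, adjusted over all protein-coding genes), and 13 of those above were in no fixed list. Lymphotoxin genes Lta and Ltb stood at 332 ± 13.9 and 79.5 ± 9.84 TPM (SD, n = 4). The haematopoietic cytokine gene Il3 was at 95.9 ± 11.2 TPM, and the TNF family ligand genes Tnfsf8, Tnfsf14, Tnfsf4 and Tnfsf9 at 95.1 ± 5.74, 56.0 ± 4.21, 54.5 ± 2.80 and 48.3 ± 6.39 TPM. Il1a, Osm and Ebi3 were at 38.3 ± 1.13, 37.8 ± 4.50 and 20.02 ± 5.31 TPM.

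Antigen receptor beta chains used many variable segments. Of 22 annotated Trbv segments 21 had a count in every library, with 2644 to 6090 counts per library in all. Trbv1 took 13.8% ± 0.811 of these counts (SD, n = 4), Trbv3 11.7% ± 0.257 and Trbv31 10.02% ± 1.09, and segments with similar sequence lose the reads they share.

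Xist and the Y-linked genes were each high in some libraries and near 0 in others, although the labels give 1 donor entry. If every library held cells of both sexes, both would be seen in each. In no library did the lower of Xist and the summed Y-linked genes exceed 0.655% of its highest library, which argues against mixed libraries. Replicates 1 and 2 had Y-linked genes and almost no Xist, and replicates 3 and 4 the reverse. These values go with cells of a single sex in each library, male in replicates 1 and 2 and female in 3 and 4. The summed Y-linked genes gave 147, 144, 0.454 and 0.295 TPM in replicates 1 to 4, and Xist 0.916, 1.01, 154 and 152 TPM. These values argue against cells of 1 sex in all 4 libraries, and so against 1 animal as their source. The labels do not give sex, so the sex of each library rests on expression alone. No biological explanation was tested, since sex was not collected.

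Of the 13 mitochondrial protein genes, 6 had under 10 counts in every library, and a candidate explanation is that reads shared with nuclear copies are left out of the counts. Set beforehand was that each of the 6 would share at least 90% of its words with another annotated gene and each of the other 7 under 50%, and this was not met: 5 of the 6 did, mt-Atp8 shares none, and mt-Co1 and mt-Nd4 share 51.1% and 62.2%. The 5 genes share at least 98.0% of their words, and multi-mapping reads were not counted, so the reads they share are missing from their counts. Judged by the condition set beforehand, the explanation stays open for the group, and for mt-Atp8. After that result, and after a search of the genome had proved impossible, the copies of the neighbours of mt-Atp8 were compared instead: Gm28661 (of mt-Co2) and Gm10925 (of mt-Atp6) begin 914 bases apart on chromosome 1, a difference of 0 bases from mt-Co2 and mt-Atp6, so an unannotated copy of mt-Atp8 may lie between them, though equal distance does not show equal sequence. No biological explanation was tested.

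The labels name total RNA while the linked protocol names poly(A) selection. The 13 replication-dependent histone genes with at least 80% unique words had a median of 1.76 TPM in the library where it was highest and 0.647 TPM where it was lowest, while Pcna and Rrm2, expressed in S phase, stood at 743 and 629 TPM. This meets the median under 10 TPM in every library that had been set beforehand for poly(A)-selected libraries. The filter by unique words favours long annotated transcripts, such as Hist1h1d with 7376 words and Hist1h2be with 4443, beside short ones such as Hist1h1a with 692. TPM divides by exon length, so the filter may itself lower the median, which cannot decide the preparation. Against poly(A) selection stand Rpph1 at 122 TPM and Snora73b at 116 TPM, RNAs without a poly(A) tail, although both share most of their words with other genes. H1f0, not tied to replication, was among the 13 by its symbol. The preparation stays open, and no biological explanation was tested.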
